A study of Drosophila melanogaster with 22 samples.

How the data were processed

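RNA was measured by sequencing of polyA-selected, strand-specific libraries from anterior ovarioles of virgin Drosophila melanogaster females of the w1118 strain, a white-eyed laboratory strain, at ages of 1 to 8 days after eclosion. An anterior ovariole holds the germarium, where the germline and follicle stem cells reside, and young egg chambers. Per the labels' protocols, 30 to 50 ovarioles went into a sample, 200 ng of total RNA into a library, and ERCC RNA controls, a set of 96 synthetic transcripts, were added during library preparation. Ovarioles of days 1 to 4 were dissected up to stage 8 egg chambers and those of days 5 to 8 up to stage 7, so that age and dissection coincide between these age series.

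The deposited values are raw counts of reads per annotated feature, 1 column per library, in whole numbers and with no normalization. Per the submitters' processing notes the tools were CASAVA 1.8.2, HISAT2 2.0.1, SAMtools 0.1.2 and HTSeq 0.6.1p1, and the annotation deposited by the authors is FlyBase release 6.07 with the ERCC sequences. Reads were 76 nt long, from single ends. The table of the whole series holds the same counts as the 22 sample files. Each file lists 19146 features: 17478 genes, all of which matched a symbol in the deposited annotation, 1572 features with identifiers of natural transposon insertions (FBti), and the 96 spike-in transcripts. The insertion features are absent from the annotation and name no gene. They held 1.46 to 4.11% of the counts of a library and stayed out of library sizes and tests, as did the spike-in transcripts. How reads that match several features were counted is not given in the sources used here, so counts of closely related gene copies are uncertain.

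The labels give 2 libraries for each of days 1 and 4 and 3 for each other day, described as independent biological replicates. Gene counts per library ranged from 1146915 to 9781870 in days 1 to 4 and from 2975582 to 4634327 in days 5 to 8, so that 3 counts correspond to 0.307 to 2.62 CPM, counts scaled to the gene total of a library. No pair of replicates was the same library deposited again: over genes with at least 10 counts, the chi-square per degree of freedom between replicates was at least 3.91. Intervals for shares of counts are 95% Wilson intervals. Such intervals and floors cover counting error only.

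Genes were tested with edgeR 4.0.16 (TMM normalization, quasi-likelihood F-tests, a coefficient per day over all 22 libraries) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The default filter on low counts (minimum count 10) left 8024 genes. The residual degrees of freedom were 14 and the common biological coefficient of variation was 23.2%. The comparisons were any difference among days 1 to 4, any difference among days 5 to 8, day 4 against day 1, day 8 against day 5, the difference between these last changes, the mean of days 5 to 8 against the mean of days 1 to 4, and each step between consecutive days. CPM are computed here from the deposited counts with TMM library sizes. Fold changes are on the log2 scale, later days against earlier days. The comparisons, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined.

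A total of 34 gene lists covered germline and somatic cells of the ovary, eggshell and yolk, other tissues, hormones, stress and basic cell functions. The 31 lists with at least 3 tested genes were tested as sets with camera of limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation between genes of 0.01 and again with an estimated correlation. Adjustment was over the lists of a comparison. The share of spike-in counts was compared among days by exact permutation tests of the between-day sum of squares of its log10, separately in each age series.

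Genes were named by a fixed rule. For day 4 against day 1, day 8 against day 5 and the means of the age series, these were the 10 largest rises and the 10 largest falls among called genes with a mean of at least 5 CPM and no overlap between the libraries of the sides compared. For tests of any difference they were the 5 smallest p-values, for steps of a day and for the difference of changes the 2 largest rises and 2 largest falls, and for each list up to 4 called members with the largest change or, with none called, the most abundant member. Markers of late egg chambers and of other tissues could be named at any level.

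On counts simulated from the real means, with 50 genes changed at each fold and 8024 genes tested, the edgeR fit recovered 22% of 2-fold and 62% of 4-fold changes for day 4 against day 1, 56% and 72% for day 8 against day 5, and 84% and 94% for the means of the age series. Alternatives were DESeq2 1.42.0, DESeq2 size factors in edgeR, no filter on low counts or a filter of 1 CPM in 6 libraries (8248 genes), the replicate number as a block, the eggshell level as a covariate, fits within an age series, a linear trend and leaving out each library. Further alternatives, chosen after the data were seen, treated 3 libraries with almost no spike-in counts. Gene coordinates are those of the deposited annotation.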

Results

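The 22 libraries profile polyA RNA of hand-dissected anterior ovarioles on each of the first 8 days of adult life, with 2 libraries on days 1 and 4 and 3 libraries on every other day. Gene counts per library ranged from 1146915 to 9781870 (n = 10) in days 1 to 4 and from 2975582 to 4634327 (n = 12) in days 5 to 8. Between 8679 and 10570 genes had a count in a library. The libraries of days 5 to 8 resembled one another whatever their age, with a median Pearson correlation of log2 CPM across genes of 0.970 between libraries of the same day and 0.970 between libraries of different days. In days 1 to 4 the median correlation of libraries of the same day was 0.946.

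The libraries of days 1 to 4 were of 2 kinds. Day 2 replicate 1, day 3 replicate 2 and day 4 replicate 2 held only 31, 19 and 52 spike-in counts, while the other 19 libraries held at least 25577. The same 3 libraries had 0.0425 to 0.0544% of their gene counts on small nucleolar and small nuclear RNAs, which guide modification of ribosomal RNA and splicing, against 0.178 to 0.412% in the other 7 libraries of days 1 to 4 and 0.0342 to 0.102% in days 5 to 8. Mitochondrially encoded genes held 1.17 to 2.72% of gene counts in the 3 libraries and 0.536 to 1.02% in the other 7. Day 4 replicate 1 had the highest share of spike-in counts, 42.7% of all counts (95% Wilson interval 42.7 to 42.8%).

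The share of spike-in counts measures polyA RNA of the ovary against the control RNA only if each library received equal control RNA. This cannot be assumed in days 1 to 4, where the means of days 2, 3 and 4 pool libraries with and without spike-in. On day 2 the share was 0.00032, 11.9 and 2.67% in replicates 1, 2 and 3. It averaged 3.87% ± 0.238 (SD, n = 2) on day 1, 4.87% ± 6.27 (n = 3) on day 2, 1.24% ± 1.12 (n = 3) on day 3 and 21.7% ± 30.7 (n = 2) on day 4, of spike-in plus gene counts. It was 1.01% ± 0.0919 on day 5, 1.23% ± 0.404 on day 6, 1.65% ± 0.407 on day 7 and 1.65% ± 0.357 on day 8 (SD, n = 3 each). No difference among days 5 to 8 was called (p = 0.116 over 369600 arrangements, exact permutation test of the log10 share, sum of squares, so without a side). In days 1 to 4 the 3 libraries with almost no spike-in counts set the spread within days 2, 3 and 4, so the same exact permutation test (p = 0.935 over 25200 arrangements) could not show a difference and none is ruled out.

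The first comparison asks how anterior ovarioles change between day 1 and day 4 after eclosion. The muscle actin gene Act57B (FBgn0000044; 2R, 20944021 to 20946431) fell from 384 ± 19.1 to 94.7 ± 24.8 CPM (SD, n = 2 each), by 2.04 ± 0.34 (SE) on the log2 scale (edgeR adjusted p = 0.0356). CG4198 (FBgn0029753; X, 5313258 to 5315190) rose from 5.98 ± 1.71 to 30.6 ± 8.12 CPM (log2 2.29 ± 0.40, SE, adjusted p = 0.0395), and CG9914 (FBgn0030737; X, 16306912 to 16308667) fell from 38 ± 2.16 to 13.2 ± 1.50 CPM (log2 -1.50 ± 0.27, SE, adjusted p = 0.0451). These were the 3 genes that edgeR called among 8024 (1 higher, 2 lower; 921 at an unadjusted p under 0.05), and DESeq2 called 13. A fit of the libraries of days 1 to 4 alone called 0. No gene was called without day 1 replicate 1 or without day 1 replicate 2, where the lone library of that day is assumed to vary like the others. Without day 4 replicate 1, 5 genes were called, but not CG4198 and CG9914 (adjusted p = 0.0842 and 0.112), and without day 4 replicate 2 neither Act57B nor CG9914 passed (0.164 for each). Without the 3 libraries lacking spike-in, where day 4 is replicate 1 alone and is assumed to vary like the other days, the adjusted p was 0.101 for Act57B and 0.147 for CG9914.

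Among the 16 muscle genes, which encode contractile and sarcomere proteins, 1 was called over all genes and 7 fell when adjusted over the list alone, and all 16 estimates were negative (median log2 -1.17, camera adjusted p = 1.44e-08, adjusted p = 0.871 with an estimated correlation). Summed over the list, muscle genes made up 3814 ± 253 CPM on day 1, 1870 ± 746 on day 2, 1620 ± 668 on day 3 and 2200 ± 1704 on day 4 (SD, n = 2, 3, 3 and 2). The day 4 libraries were far apart, at 3405 CPM in replicate 1 and 995 CPM in replicate 2, which lacks spike-in. Myosin heavy chain, Mhc, was at 525 ± 26.1 CPM on day 1 and 224 ± 219 CPM on day 4. Without the 3 libraries lacking spike-in the list's median was -0.52, where day 4 is replicate 1 alone. The 3405 CPM of that library lie near the 3635 and 3993 CPM of the day 1 libraries. Much of the fall to day 4 thus rests on replicate 2.

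Heat shock genes, which encode chaperones that respond to unfolded protein, moved the other way. None of 10 was called over all genes, 5 rose when adjusted over the list alone, and the median was 1.47 (camera adjusted p = 0.00618, adjusted p = 0.871 with an estimated correlation). The most abundant, Hsp83, the fly Hsp90, was at 2176 ± 18.8 CPM on day 1 and 6180 ± 14.7 CPM on day 4 (log2 1.51 ± 0.44, SE). Summed over the list, heat shock genes averaged 2511 CPM on day 1 and 7033 CPM on day 4. Their sums ranged from 3731 to 8407 CPM among the libraries of day 5 and from 4049 to 11700 CPM among those of day 7. Libraries of the same age thus spread about as widely. The set call was lost without day 1 replicate 2 (camera adjusted p = 0.282), without day 4 replicate 1 (0.128) and without the 3 libraries lacking spike-in (0.0600), where the lone day 4 library is assumed to vary like the others. Mitochondrial ribosomal proteins and proteasome subunits were called higher as sets. The former had 0 of 72 genes called (0 adjusted over the list alone, median 0.34, camera adjusted p = 0.000871, adjusted p = 0.871 with an estimated correlation). The latter had 0 of 31 (0 adjusted over the list alone, median 0.22, camera adjusted p = 0.0311, adjusted p = 0.966 with an estimated correlation). Both calls were lost without the 3 libraries lacking spike-in (camera adjusted p = 0.628 and 0.815) and without day 4 replicate 2 alone (0.704 for each), settings with the same lone day 4 library, that of the proteasome also without day 1 replicate 2 (0.443). None of the other 27 lists was called as a set, and of their members only 1 juvenile hormone gene fell when adjusted over the list alone.

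Over days 1 to 4 as a whole, 2 genes differed among days. Act57B (edgeR adjusted p = 0.00125) was at 384, 120, 74.4 and 94.7 CPM on days 1, 2, 3 and 4, and CG42492 (FBgn0259994; X, 5625676 to 5648487, adjusted p = 0.0345) at 49.6, 5.82, 10.4 and 12 CPM. The muscle tropomyosin gene Tm2 (adjusted p = 0.0508), Ppn, which encodes the basement membrane protein papilin (0.0508), and CG34220 (0.0865) followed without passing. Ppn was at 393 CPM on day 1 and 91.0 CPM on day 2. edgeR called 2 genes (650 at an unadjusted p under 0.05), or 0 in a fit of days 1 to 4 alone, and DESeq2 called 55. The count was 0 without day 1 replicate 2, 1 without day 2 replicate 3 or day 3 replicate 2, and 3 without day 1 replicate 1, day 2 replicate 1 or day 2 replicate 2. It was 5 without day 3 replicate 3, 12 without day 4 replicate 1 and 47 without day 4 replicate 2. Act57B was not called without day 1 replicate 2 (adjusted p = 0.0635). CG42492 was not called without day 1 replicate 2 (0.480), day 2 replicate 1 (0.0637), day 2 replicate 3 (0.0689), day 3 replicate 1 (0.0510) or day 3 replicate 2 (0.0625).

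Between day 1 and day 2, CG5853 (FBgn0032167) fell from 74.0 ± 21.8 to 4.26 ± 1.1 CPM (log2 -3.99 ± 0.75, SE, edgeR adjusted p = 0.0466). CG42492 fell from 49.6 ± 28.7 to 5.82 ± 2.31 CPM (log2 -3.26 ± 0.52, adjusted p = 0.0160; SD, n = 2 and 3). They were among 4 genes called, all lower (844 at an unadjusted p under 0.05; 16 by DESeq2). No gene was called without day 1 replicate 2, day 2 replicate 1 or day 2 replicate 3, and 2 without day 1 replicate 1. From day 2 to day 3 edgeR called 0 genes (276 at an unadjusted p under 0.05, DESeq2 20), 1 without day 2 replicate 1 and 7 without day 3 replicate 3. From day 3 to day 4 edgeR called 0 (310, DESeq2 0), and 12 without day 4 replicate 2.

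The second comparison asks the same of older females, from day 5 to day 8. Somatic niche and escort cell genes, which act in the somatic cells that house the germline stem cells, and muscle genes were lower on day 8, and autophagy genes, which act in the degradation of cell contents, were higher. These calls of sets were lost with an estimated correlation (camera adjusted p = 0.435, 0.553 and 0.435 with an estimated correlation). At the preset correlation 8 lists were called between day 5 and day 8. Another of the 10 splits of the same libraries, which mixes the days, called 9. The count of called lists thus does not exceed that of a wrong grouping. For the niche list all 10 estimates were negative, with a median of -0.41 (camera adjusted p = 0.00202, adjusted p = 0.435 with an estimated correlation). Its most abundant member fax was at 239 ± 25.3 CPM on day 5 and 184 ± 20.7 on day 8, and Wnt4, a Wnt ligand of escort cells named after its value was seen, at 13.5 ± 1.57 and 6.17 ± 1.30 CPM (SD, n = 3 each). None of the 10 was called over all genes and 1, Wnt4, fell when adjusted over the list alone. The list's call was lost without day 5 replicate 2 (camera adjusted p = 0.0519).

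All 16 muscle genes had negative estimates on day 8 (median -0.35, camera adjusted p = 0.00202, adjusted p = 0.553 with an estimated correlation), with 0 called over all genes and 0 adjusted over the list alone. The call was lost without day 5 replicate 2 (camera adjusted p = 0.0519) and without day 8 replicate 2 (0.389). Of 16 autophagy genes 14 had positive estimates (median 0.27, camera adjusted p = 0.00202, adjusted p = 0.435 with an estimated correlation), with 0 called over all genes and 0 adjusted over the list alone. Its most abundant member ref(2)P, a receptor for cargo of autophagy, was at 169 ± 20.5 and 184 ± 45.4 CPM. The call was lost without day 5 replicate 3 (0.106) and day 8 replicate 2 (0.155).

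Proteasome genes were lower as a set (30 of 31 estimates negative, median -0.16, camera adjusted p = 0.00202, adjusted p = 0.718 with an estimated correlation), and the call was lost without day 5 replicate 3 (camera adjusted p = 0.722) and without day 8 replicate 2 (0.815). DNA replication genes (median -0.12, 0.0375, and adjusted p = 0.435 with an estimated correlation) and mitosis genes (median -0.15, 0.0464, and adjusted p = 0.499 with an estimated correlation) were lower, as were haemocyte genes, markers of blood cells (median -0.98, 0.0445, and adjusted p = 0.435 with an estimated correlation). Yolk genes were higher (median 0.83, 0.0464, and adjusted p = 0.435 with an estimated correlation). None of the members of these lists was called over all genes. Adjusted over the list alone, the yolk protein gene Yp2 rose from 14.9 ± 4.58 to 56.4 ± 21 CPM and Pxn, which encodes the matrix peroxidase peroxidasin, fell from 21.3 ± 12.9 to 5.80 ± 3.82 CPM, while 0 of the 25 replication, 18 mitosis and 31 proteasome genes passed. Of the 23 lists not called as sets, the mature follicle list had 1 gene lower and the germline stem cell list 1 gene higher when adjusted over the list alone. The calls of the replication, mitosis, haemocyte and yolk lists were each lost without day 5 replicate 1 (camera adjusted p = 0.267, 0.590, 0.187 and 0.314) and without day 5 replicate 2 (0.128, 0.270, 0.141 and 0.0519). Those of replication, mitosis and haemocytes were also lost without day 8 replicate 2 (0.202, 0.222 and 0.113), those of haemocytes and yolk without day 8 replicate 1 (0.0745 for each), and those of mitosis and yolk without day 8 replicate 3 (0.0836 and 0.217).

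No single gene passed between day 5 and day 8: edgeR called 0 (234 at an unadjusted p under 0.05), DESeq2 called 1, and edgeR called 0 without any 1 of the 6 libraries. Over days 5 to 8 as a whole the cochaperone gene DnaJ-1 (FBgn0263106; 3L, 5750029 to 5752189) was the 1 gene called (edgeR adjusted p = 0.0390; 248 at an unadjusted p under 0.05; 17 by DESeq2). It rose from 96.6 ± 2.02 CPM on day 5 to 373 ± 121 on day 6 (log2 1.95 ± 0.31, SE, adjusted p = 0.0193) and was at 269 ± 136 on day 7 and 132 ± 41.8 on day 8 (SD, n = 3 each). NaPi-III, which encodes a phosphate transporter (349 CPM on day 5 and 617 on day 7), Act57B and Yp2 had adjusted p = 0.0761 each, and CG4198 0.0969. The DnaJ-1 call over the 4 days was lost without any day 5 library (adjusted p = 0.240, 0.268 and 0.120), without any day 6 library (0.139, 0.0722 and 0.0636) and without day 8 replicate 1 or 3 (0.104 and 0.0871). DnaJ-1 was also the 1 gene called from day 5 to day 6 (211 at an unadjusted p under 0.05; 3 by DESeq2), a call lost without any day 5 library or day 6 replicate 1, and 2 genes were called without day 6 replicate 3. From day 6 to day 7 edgeR called 0 genes (223, DESeq2 3) and from day 7 to day 8 also 0 (193, DESeq2 0).

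The change from day 5 to day 8 was then tested against that from day 1 to day 4, to see whether the age series differ. No gene was called (edgeR 0, with 807 at an unadjusted p under 0.05, DESeq2 2), and 1 was called without day 4 replicate 1 or day 4 replicate 2. At the level of lists, the median difference of log2 changes was 0.72 for muscle, 0.41 for autophagy, -1.38 for heat shock, -0.36 for the proteasome and -0.35 for mitochondrial ribosomal proteins. None of these differences was called with an estimated correlation (adjusted p = 0.549 with an estimated correlation for the first 3 and 0.638 for the others). The autophagy median was -0.31 from day 1 to day 4 and 0.27 from day 5 to day 8, and that of the proteasome 0.22 and -0.16. The list tests of the difference were not repeated with any library left out, and day 4 replicate 2 lacks spike-in.

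The third comparison sets days 5 to 8 against days 1 to 4. Eggshell transcripts were far lower in the older series. Chorion genes encode the outer eggshell, which follicle cells make late in oogenesis, in stages after those dissected, and all 10 tested fell (10 adjusted over the list alone, median log2 -5.39, camera adjusted p = 3.28e-18, adjusted p = 0.00217 with an estimated correlation). Cp38 (FBgn0000360; X, 8481837 to 8483311) fell from 126 ± 88.0 to 1.89 ± 1.60 CPM. Cp36 (FBgn0000359; X, 8479319 to 8480523) fell from 87.3 ± 69.0 to 1.68 ± 2.35 CPM (SD, n = 10 and 12). These are log2 changes of -5.75 ± 0.40 and -5.72 ± 0.50 (SE, edgeR adjusted p = 7.34e-09 and 1.32e-07). Cp7Fc (log2 -6.32) and Cp7Fb (-6.23), in the same gene cluster, fell from 17.5 ± 20.6 and 18.2 ± 21.7 CPM to 0.224 ± 0.368 and 0.256 ± 0.442 CPM, which rest on 10 and 11 counts over the 12 later libraries. All 4 lay below every library of days 1 to 4 in every library of days 5 to 8. Summed over the list, chorion genes held 330, 1133, 477 and 341 CPM on days 1 to 4 and 23.4, 5.68, 17.3 and 12.5 CPM on days 5 to 8.

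**Figure D1:**
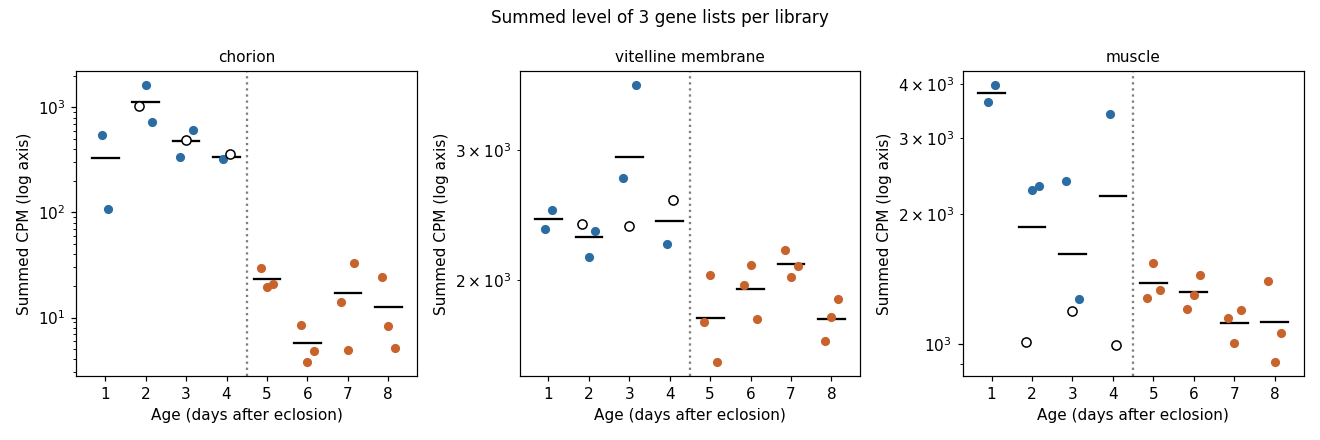
Summed CPM (log axes) of the chorion, vitelline membrane and muscle lists in each library against age in days after eclosion. Points are libraries (blue, days 1 to 4; orange, days 5 to 8; open, the 3 libraries without spike-in), short lines are means of a day, and the dotted line separates the dissections. Chorion sums lie between 108 and 1647 CPM in days 1 to 4 and between 3.77 and 32.7 CPM in days 5 to 8.

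Genes of the vitelline membrane, the inner eggshell layer, and of yolk were lower as well. Of 10 vitelline membrane genes 6 fell (7 adjusted over the list alone, median -1.17, camera adjusted p = 1.07e-06, adjusted p = 0.0110 with an estimated correlation). Among them were Vm26Aa, from 151 ± 116 to 13.3 ± 21 CPM, Vm34Ca, from 121 ± 81.9 to 12.3 ± 17.3 CPM, and Vm26Ab, from 294 ± 262 to 95.2 ± 61.1 CPM. Vm32E (log2 -5.27 ± 1.27, SE) lost its call without day 1 replicate 1 (adjusted p = 0.111). The yolk protein genes Yp1 (log2 -2.76), Yp2 (-2.70) and Yp3 (-1.16) fell, while yl, which encodes the yolk receptor of the oocyte, was not called. In this list 3 of 4 genes were lower (3 adjusted over the list alone, camera adjusted p = 0.00171, adjusted p = 0.151 with an estimated correlation). Its median was -1.92 against the libraries of days 2 to 4 with spike-in and -0.76 against the 3 without. Summed over the list, with yl included, it held 4600 ± 772 CPM in days 1 to 4 and 4228 ± 446 CPM in days 5 to 8 (SD, n = 10 and 12). In the mature follicle list, sim fell (log2 -0.89) and Mmp2, a matrix metalloproteinase, rose (1.22; 1 higher and 1 lower of 5, and 1 and 2 adjusted over the list alone, camera adjusted p = 0.246).

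Muscle genes, and single genes of haemocytes and neurons, were lower as well. Of 16 muscle genes 13 fell (16 adjusted over the list alone, median -1.26, camera adjusted p = 5.87e-13, adjusted p = 0.140 with an estimated correlation). The largest falls were those of the troponin gene up (log2 -1.49), the titin gene sls (-1.44), the myosin light chain gene Mlc1 (-1.41) and the actin gene Act87E (-1.36). The calls of Mlc1 and Act87E were lost without day 4 replicate 1 (adjusted p = 0.0509 and 0.0599). The muscle genes summed to 2250 ± 1130 CPM in days 1 to 4 and 1237 ± 186 CPM in days 5 to 8 (SD, n = 10 and 12). The 3 libraries without spike-in lay at 995 to 1196 CPM, below the mean of days 5 to 8, while their chorion sums were 362 to 1021 CPM. Haemocyte markers Hml (log2 -1.82), Pxn (-1.09) and crq (-0.46) fell, 3 of 4 tested (1 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.0958). Of 9 neuronal genes cpx, which encodes the synaptic protein complexin, fell (-2.77; 2 lower adjusted over the list alone, camera adjusted p = 0.0620). The median of the neuronal list was -1.06 against the libraries of days 2 to 4 with spike-in and 0.61 against the 3 without. The calls of Hml and cpx were lost without day 4 replicate 1 (adjusted p = 0.0931 and 0.102) or day 1 replicate 1 (0.0701 and 0.0609). That of Hml was also lost without day 2 replicate 2, day 3 replicate 1 or day 6 replicate 3 (0.0544, 0.0530 and 0.0556). Those of Pxn and crq were lost when any 1 of 14 and 13 of the 22 libraries was left out. None of 7 gut enzyme genes was called (0 adjusted over the list alone, camera adjusted p = 0.246). The 1 fat body gene tested, Rfabg, was at 65.5 ± 31 and 66.0 ± 23.5 CPM, none of the 2 tested immune effector genes was called, and no testis gene passed the filter on low counts. Day 4 replicate 1 had the highest sums of the neuronal (276 CPM), gut (136), fat body (147) and immune effector (43.6) lists of all libraries.

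Of 84 cytosolic ribosomal protein genes 34 rose and none fell (47 adjusted over the list alone, median 0.28, camera adjusted p = 2.76e-24, adjusted p = 0.415 with an estimated correlation). RpS26 (FBgn0261597; 2L, 18441335 to 18443277) rose from 2169 ± 279 to 3299 ± 355 CPM (log2 0.63 ± 0.08, SE, edgeR adjusted p = 1.36e-05), RpS29 by 0.54, RpS24 by 0.54, RpL28 by 0.50 and RpL23A by 0.48. The translation factors pAbp, the polyA-binding protein (log2 0.54 ± 0.06, SE), and EF2, an elongation factor (0.34), rose in the same libraries. Nuclear genes of oxidative phosphorylation rose in 11 of 68 cases (14 adjusted over the list alone, median 0.14, camera adjusted p = 2.95e-08, adjusted p = 0.415 with an estimated correlation), among them COX8 (0.35), ATPsynB (0.32), ND-B22 (0.31), COX7C (0.31) and ND-75 (0.30). COX8 and COX7C lost their calls when any 1 of 5 and 6 libraries was left out. So did ATPsynB without day 1 replicate 2 or day 4 replicate 1 (adjusted p = 0.0679 and 0.0590), and ND-B22 without day 1 replicate 1 (0.0663). None of the 12 mitochondrially encoded mRNAs was called (0 adjusted over the list alone, camera adjusted p = 0.145) over both kinds of library in days 1 to 4. Of 72 mitochondrial ribosomal protein genes 2 rose, mRpS30 and mRpL55 (0 adjusted over the list alone, median 0.06, camera adjusted p = 0.0181, adjusted p = 0.735 with an estimated correlation). The list was no longer called without day 3 replicate 1, day 4 replicate 1 or day 8 replicate 3 (camera adjusted p = 0.115, 0.46 and 0.0655). mRpS30 and mRpL55 lost their calls when any 1 of 14 and 5 libraries was left out.

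**Figure D2:**
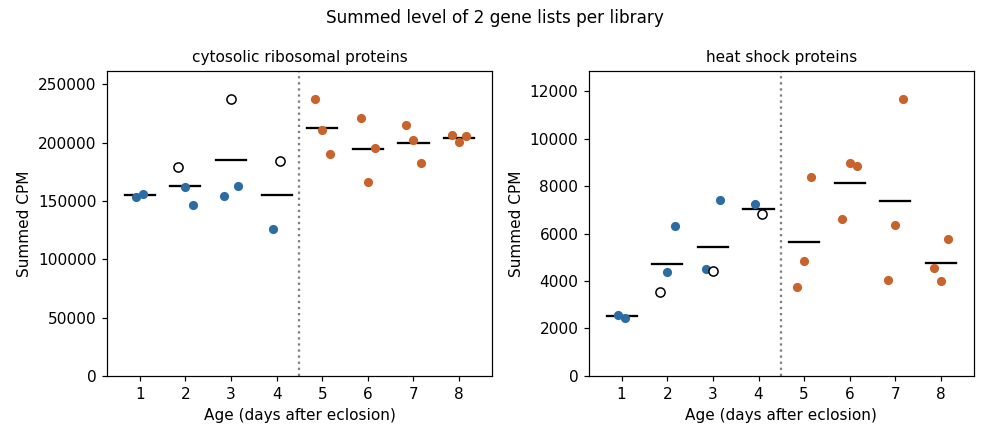
Summed CPM (linear axes from 0) of cytosolic ribosomal protein and heat shock genes in each library against age in days after eclosion, drawn as points per library with means of a day as short lines (open points, the 3 libraries without spike-in). Ribosomal protein genes sum to 166100 ± 29900 CPM in days 1 to 4 and 202900 ± 18410 CPM in days 5 to 8 (SD, n = 10 and 12).

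The size of several of these differences depended on the kind of library in days 2 to 4. A fit chosen after the data were seen gave each day and kind its own mean, and set days 5 to 8 against the 5 libraries of days 2 to 4 with spike-in or the 3 without. Each of the 3, and day 4 replicate 1, stands alone in its day and kind and is assumed to vary like the other groups. The set tests of this fit used only the preset correlation of 0.01. The median of the ribosomal protein genes was 0.49 against the libraries with spike-in (77 of 84 higher) and 0.00 against the 3 without (12 higher, 12 lower). Chorion genes were lower against both kinds, with medians of -5.66 (10 lower) and -4.89 (9 lower). Muscle genes had medians of -1.02 (10 lower) and -0.45 (1 higher and 1 lower, camera adjusted p = 0.145). Nuclear oxidative phosphorylation genes had a median of 0.27 (18 higher) against libraries with spike-in and -0.02 (6 higher, 2 lower) against those without. For mitochondrially encoded mRNAs the direction turned, from 0.50 (5 higher, camera adjusted p = 0.00651) to -0.46 (3 lower, camera adjusted p = 0.0327). It turned for mitochondrial ribosomal proteins as well, from 0.16 (6 higher, camera adjusted p = 0.000206) to -0.21 (3 lower, camera adjusted p = 0.00138). Small nucleolar and nuclear RNAs, of which 47 of 100 fell in the whole comparison, had medians of -2.31 (61 lower) and 1.38 (24 higher and 1 lower). Among the largest falls in days 5 to 8 were ribosomal RNA pseudogenes and fragments, 28SrRNA-Psi:CR40741 (log2 -3.21), CR40712 (-3.07), CR40640 (-3.04), CR41607 (-3.00), 28SrRNA-Psi:CR45848 (-2.98) and CR40621 (-2.88). They share sequence with other ribosomal RNA copies, so their separate values are uncertain.

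**Figure D3:**
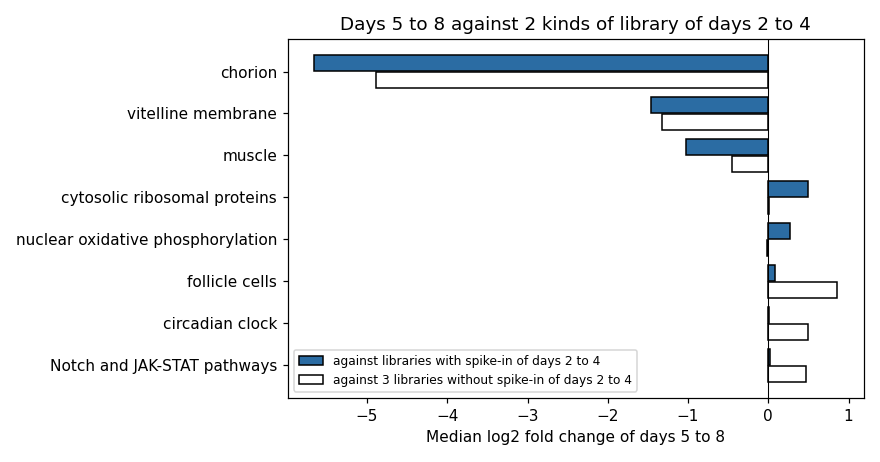
Median log2 fold change of 8 gene lists in days 5 to 8 against the 5 libraries of days 2 to 4 with spike-in (filled bars) and against the 3 libraries of those days without (open bars). The bars of the muscle list are -1.02 and -0.45, and those of the chorion list -5.66 and -4.89.

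Among germline genes, a few transcripts that the oocyte stores fell. Of 15 maternal and oocyte mRNAs 3 rose and 4 fell (3 and 5 adjusted over the list alone, camera adjusted p = 0.548). Those lower included pgc (log2 -0.79), which silences transcription in germ cells, the anterior determinant bcd (-0.43) and swa (-0.33), which is needed to localize bcd RNA, and grk, the oocyte's ligand for the EGF receptor, was higher (0.32). The translational repressor nos fell (-0.50; 1 of 11 germline stem cell genes, 1 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.496). Of 18 meiotic genes 3 fell (3 adjusted over the list alone, camera adjusted p = 0.172), mei-W68, the enzyme that makes meiotic double-strand breaks (-0.96), mtrm, an inhibitor of Polo kinase (-0.59), and the kinesin gene nod (-0.50). The meiotic phosphatase gene twe (-1) and CycB3 (-0.38) fell among 18 mitosis genes (2 adjusted over the list alone, camera adjusted p = 0.0438, adjusted p = 0.415 with an estimated correlation). Of 25 piRNA genes fs(1)Yb, which acts in somatic cells, rose (0.76; 1 adjusted over the list alone, camera adjusted p = 0.0181, adjusted p = 0.151 with an estimated correlation). Of 25 replication genes 2 rose, Mcm6 and dpa, while Cdc6 and CycE fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.820). Without the 3 libraries lacking spike-in nos, pgc and swa were not called (adjusted p = 0.0895, 0.175 and 0.0623). The genes bcd, grk and nos were not called without day 1 replicate 1 (0.0685, 0.0648 and 0.1), grk also without day 4 replicate 1 (0.0563). Nor were nos, pgc and swa called without day 4 replicate 2 (0.0501, 0.0676 and 0.0885), or swa without day 1 replicate 1 or day 1 replicate 2 (0.0566 and 0.0688). CycE was not called without day 4 replicate 1 (0.0551), nor Mcm6 without day 1 replicate 2 or day 4 replicate 1 (0.0584 and 0.0581). The calls of mei-W68, dpa and the mitosis list were lost when any 1 of 14, 12 and 13 libraries was left out.

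Somatic and signalling genes gave a mixed picture. The follicle cell regulators eya (log2 0.53) and tj (0.40) rose, 2 of 11 follicle cell genes (5 adjusted over the list alone, median 0.28, camera adjusted p = 0.0181, adjusted p = 0.571 with an estimated correlation). eya was not called without day 1 replicate 1 (adjusted p = 0.0594). The follicle cell list was called no longer without day 2 replicate 1, day 3 replicate 2 or day 4 replicate 2 (camera adjusted p = 0.0660, 0.0559 and 0.141). These are the 3 libraries lacking spike-in, which had it lower than the other libraries of days 1 to 4 (camera adjusted p = 1.28e-05, at the preset correlation only). Set against the libraries of days 2 to 4 with spike-in the list's median was 0.08 (0 called, camera adjusted p = 0.978), and against the 3 without 0.86 (9 higher, camera adjusted p = 7.67e-07). Notch and JAK-STAT genes were higher as a set (0 of 11 called, 3 adjusted over the list alone, camera adjusted p = 0.0411, adjusted p = 0.487 with an estimated correlation). Autophagy genes were lower (0 of 16, and 0 adjusted over the list alone, 0.0373, adjusted p = 0.441 with an estimated correlation). Neither was called without the 3 libraries lacking spike-in (camera adjusted p = 0.501 and 0.189), or when any 1 of 8 and 9 libraries was left out. The clock gene per rose from 48.7 ± 18.9 to 95.3 ± 14.1 CPM (log2 1.00 ± 0.16, SE, edgeR adjusted p = 0.000479), the 1 gene called of 8 clock genes (2 adjusted over the list alone, camera adjusted p = 0.0518). The median of the clock list was 0.0125 against the libraries of days 2 to 4 with spike-in and 0.49 against the 3 without. Its size thus depended on the kind of library. Jheh3, which encodes a hydrolase that degrades juvenile hormone (1.48), and gce, a receptor of that hormone (0.45), rose among 6 genes (2 adjusted over the list alone, camera adjusted p = 0.0933).

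In the ecdysone response list, the hormone-degrading enzyme gene Cyp18a1 (log2 0.73) and the nuclear receptor gene Eip75B (0.51) rose, and Hr4 (-1.08) and usp (-0.27) fell, 4 of 12 genes (2 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.820). The list's median was -0.08 against the libraries of days 2 to 4 with spike-in and 0.32 against the 3 without. Its direction thus depended on the kind of library. The glutathione transferase gene GstE9 rose (1.24) and GstD1 fell (-0.33) among 22 detoxification genes (1 and 1 adjusted over the list alone, camera adjusted p = 0.340). The cell death activator hid rose (0.79; 1 of 6 apoptosis genes, 2 adjusted over the list alone, camera adjusted p = 0.577). The proteasome gene Rpn1 rose (0.36; 1 of 31, 0 adjusted over the list alone, camera adjusted p = 0.383). The small chaperone gene Hsp27 fell (-0.70; 1 of 10, 1 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.496). None of the 10 niche, 8 ecdysone synthesis and 14 insulin and TOR genes was called over all genes or adjusted over the list alone (camera adjusted p = 0.626, 0.953 and 0.604). The call of Hr4 was lost when any 1 of 18 libraries was left out (log2 -0.37 without day 4 replicate 1). The calls of Rpn1, GstD1, usp, Hsp27 and Cyp18a1 were lost in the same way for 15, 10, 9, 8 and 7 libraries.

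**Figure D4:**
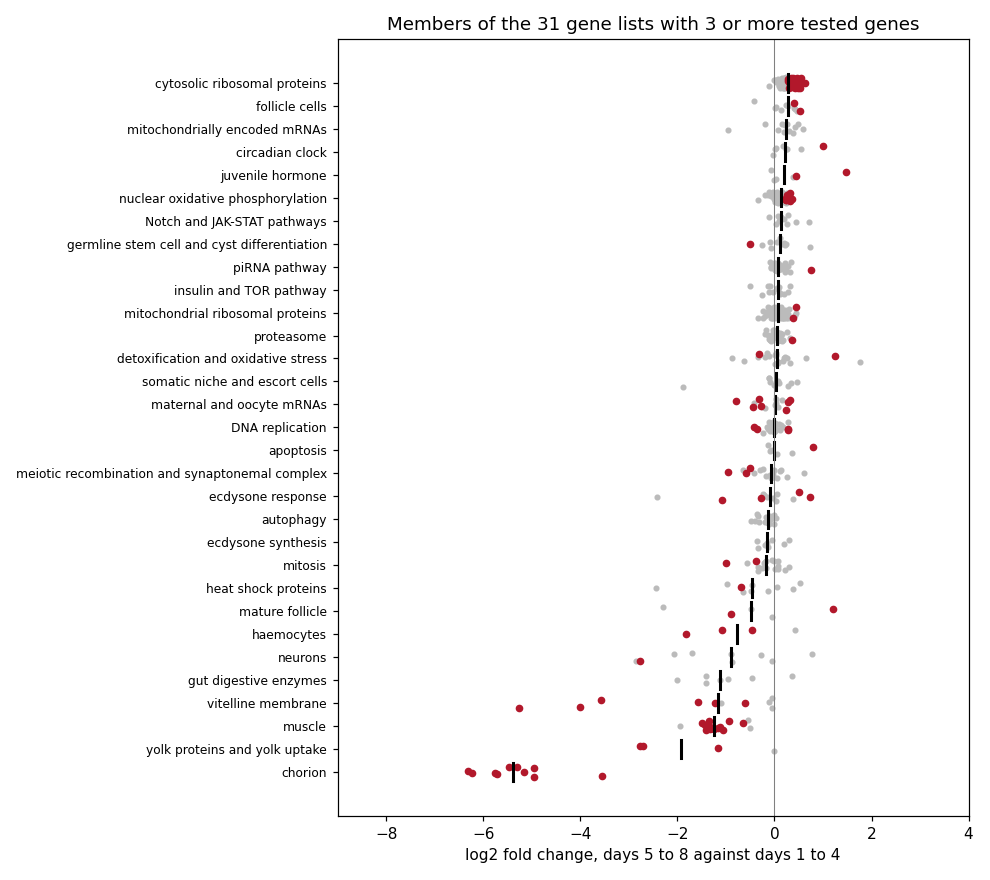
Log2 fold changes of days 5 to 8 against days 1 to 4 for the tested members of 31 gene lists, ordered by their median. Red points are called genes (adjusted p under 0.05 over all genes), grey points are the rest and black bars are medians, from -5.39 for the chorion list to 0.28 for the cytosolic ribosomal proteins.

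In all, 708 of 8024 genes were called by edgeR between the age series, 326 higher and 382 lower in days 5 to 8 (1900 at an unadjusted p under 0.05, DESeq2 884). For 29 of these the libraries of the series did not overlap, and besides the genes above they included Ten-a, a teneurin of the cell surface (log2 0.88), the planar polarity gene Vang (0.48) and Cul4, a scaffold of ubiquitin ligases (0.48). The count was 401 without day 1 replicate 1, 1143 with a term for the 3 libraries lacking spike-in (543 of the 708 among them) and 1157 without them (540). Age, the dissected stage and the separate deposition of the series change together here and cannot be told apart in this comparison. Nor can a difference in library preparation. The 7 libraries of days 1 to 4 with spike-in had 1146915 to 2573634 gene counts, against 2975582 to 4634327 in days 5 to 8. Small nucleolar and nuclear RNAs held 0.178 to 0.412% of these counts, against 0.0342 to 0.102%. When libraries were scaled by spike-in counts, which 19 libraries allow and where day 4 is replicate 1 alone, with its 43.5% of spike-in in spike-in plus gene counts, the median of all genes moved to 2.35 and 7645 of 7703 called genes were higher, so directions in this comparison are relative to the median gene.

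The step from day 4 to day 5 crosses from the earlier dissection to the later. Cp38 fell from 142 ± 34.5 to 1.53 ± 0.776 CPM (log2 -6.50 ± 0.82, SE, edgeR adjusted p = 0.000266). Cp36, Yp1 and Yp2 fell with it, Yp1 from 325 ± 433 to 19.4 ± 6.55 CPM and Yp2 from 150 ± 178 to 14.9 ± 4.58 CPM (SD, n = 2 and 3). For both yolk genes the SD of day 4 exceeded the mean, so 1 of its 2 libraries carried most of that mean. CG15570 (FBgn0029697), at 30.1 ± 8.85 CPM on day 4, had 3 counts over the day 5 libraries (adjusted p = 0.0492). RpS26 was the 1 gene that rose, from 1810 ± 155 to 3506 ± 527 CPM (log2 0.95 ± 0.16, SE, adjusted p = 0.00794). These belong to 19 genes called, 18 of them lower (803 at an unadjusted p under 0.05). DESeq2 called 60, 24 higher and 36 lower. With a term for the 3 libraries lacking spike-in 133 genes were higher and 173 lower, and without those libraries 138 and 201, where day 4 is replicate 1 alone and is assumed to vary like the other days. The count was 5 without day 4 replicate 1, 107 without day 4 replicate 2, 7 without day 5 replicate 1, and 8 without day 5 replicate 2 or day 5 replicate 3, and RpS26 was not called without day 4 replicate 1 (0.258) or day 5 replicate 1 (0.0534).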

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

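The comparison of the changes over both age series was planned, and the tests of gene length and of thinned libraries were chosen before their results were seen. The other tests of technical explanations in this part were chosen only after the result was seen.

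For 7 gene lists the change from day 5 to day 8 differed from that from day 1 to day 4 by a test of the difference itself (camera, adjusted over 31 lists). The adjusted p was 0.000999 for muscle, 0.000999 for mitochondrial ribosomal proteins and 0.000999 for the proteasome. It was 0.0149 for autophagy, 0.0234 for yolk proteins (median difference 1.04), 0.0234 for heat shock proteins and 0.0234 for DNA replication (-0.15). None of them passed camera with an estimated correlation, where the adjusted p was 0.549 or 0.638. These list tests were not repeated with any library left out. Of the day 4 libraries, replicate 2 lacks spike-in. In replicates 1 and 2 of day 4, muscle genes summed to 3405 and 995 CPM. Mitochondrial ribosomal genes summed to 2358 and 3465 CPM, and proteasome genes to 3518 and 4133 CPM. For these lists the kind of library may thus enter the difference. Features with identifiers of transposon insertions, which name no gene and entered no comparison, held a median of 1.82% of the counts of a library, and 1484 of 1572 had a count.

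The 3 libraries without spike-in differ from the other 7 of days 1 to 4 in 1489 of 7248 genes with day in the fit (492 higher and 997 lower, edgeR), and 71 of 83 small nucleolar and nuclear RNAs were lower, with a median of -3.62. Greater depth of the 3 libraries is argued against: thinned to 1401047 counts each they still gave 1314 calls among 6950 genes, 1229 of them called before. A batch of library preparation remains a candidate explanation: although they come from 3 different days, the lowest of their mutual correlations was 0.977, above the 0.957 that was the highest with a library of their own day. These correlations used unthinned counts, with 3648865 to 9781870 gene counts in the 3 libraries and 1146915 to 2573634 in the other 7. With the libraries of days 5 to 8 the 3 correlated at a median of 0.959 (at most 0.969), also above 0.957. The correlations by themselves therefore do not separate a batch from depth. The labels name no such batch, and no biological group of the design holds these 3 libraries.

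Chorion genes fell between the age series, with a median of -5.39 on the log2 scale. A gradual change with age is argued against by the slope within the series, -0.115 per day (SE 0.159) for the mean log2 CPM of the list, where the difference of -4.02 between the series would need -1.01 per day. The 3 libraries without spike-in are not the cause, since the median was -5.44 without them (camera adjusted p = 4.64e-12). A step of -3.08 from day 4 to day 5 lies where the dissection changed from stage 8 to stage 7. Chorion is made after both stages, so the dissection would account for the step only if later chambers were carried over in days 1 to 4, which was not tested. An abrupt change with age or a difference in preparation between the series cannot be told apart from it, because these coincide with the dissection.

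The ribosomal protein genes rose by a median of 0.28 between the age series. Gene length bias is argued against: other genes of at least 50 CPM matched on exon length (median 923 nt, against 921.5 nt in the list) had a median of 0.0506, with 95% of 1000 draws between 0.000934 and 0.0967. The 3 libraries without spike-in do not produce the rise, since it was 0.48 without them. Library preparation that differed between the series may do so, since in days 1 to 4 the 3 libraries without spike-in exceeded the other 7 by a median of 0.469, more than the series differ. Age and the dissected stage remain open beside it and were not tested separately.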

How the results depend on the processing

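Alternatives for libraries without spike-in were chosen only after the data were seen, as was scaling by spike-in counts on 19 libraries; the planned scaling of all 22 was not run, since 3 libraries have almost no spike-in counts. Day 8 against day 5 and the share of spike-in counts kept their side of the threshold unless named here, and the cause of a change was not tested unless given.

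DESeq2 called 55 genes for any difference in days 1 to 4 (2 by edgeR), 17 in days 5 to 8, 13 for day 4 against day 1, 1 for day 8 against day 5, and 2 for the difference of changes. It called 16, 20, 60, 3 and 3 for days 2 against 1, 3 against 2, 5 against 4, 6 against 5 and 7 against 6. No filter on low counts, which let in genes with few counts, gave 275, 135, 121, 26 and 107 for the first 5 of these, and 154, 65, 50, 180, 34, 42 and 27 for the steps from day 1 to day 8. Within its own series, any difference gave 0 in days 1 to 4 and 4 in days 5 to 8, and day 4 against day 1 gave 0. DESeq2 size factors, the filter of 1 CPM in 6 libraries, which let in 8248 genes, and the linear trend moved no count by over 1.5 times.

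The labels link same-numbered libraries by nothing but the number. Over 71 pairs the median correlation of deviations was 0.0492 (-0.506 to 0.387, 25 over 0.1). Within days 5 to 8 most pairs were positive, those of replicate 3 at 0.113 to 0.236, but those of replicate 2 went down to -0.0656. Both extremes came from pairs among days 2 to 4, which hold the 3 libraries without spike-in. Of the libraries, 15 of 22 correlated best with their own number, a hint from the data, for which no chance rate was computed. On each of days 5 to 8 replicate 3 had the highest sum of the proteasome list (5303, 4345, 4124 and 4589 CPM). The same held for mitochondrial ribosomal proteins (3332, 3108, 3073 and 3305 CPM). The main fit has no term for the replicate number. With the replicate block day 4 against day 1 gave 11, any difference in days 5 to 8 gave 2, the difference of changes 1 and day 3 against day 2 gave 2. The list count was 20 against 24. The block ended the calls of CG42492 among days 1 to 4 (adjusted p = 0.0524, edgeR) and, for the means of the series, of Pxn (0.0659), crq (0.0696), Hr4 (0.0795), Cyp18a1 (0.0551) and dpa (0.0506). It also ended those of the follicle cell and mitochondrial ribosomal lists (camera adjusted p = 0.0510 for each) and of the mitosis, autophagy and Notch and JAK-STAT lists (0.0632 for each).

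With the eggshell level as a covariate, which nearly coincides with the series, the means of the series gave 0 genes, day 4 against day 1 gave 1 and 12 lists were called. The covariate is the mean log2 CPM of the chorion and vitelline membrane lists. Losses or reversals of these lists and their genes were therefore built in and do not test them. In the comparison of the means of the series it reversed Cp7Fb (1.62), Vm34Ca (0.98), grk (-0.0590), mtrm (0.11), Act87E (0.54), cpx (0.60), Hsp27 (0.19), Cyp18a1 (-0.75), Eip75B (-0.0131), gce (-0.20), hid (-0.35) and the chorion (0.39), follicle cell (0.0598) and Notch and JAK-STAT lists (-0.10). An estimated correlation left 2 lists, chorion and vitelline membrane.

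A term for the 3 libraries lacking spike-in gave 1 gene in days 1 to 4, 5 in days 5 to 8, 1143 for the means of the series, 4 for day 3 against day 2 and 306 for day 5 against day 4. Without them the counts were 16, 5, 1157, 1 and 339, with 1 for the difference of changes, 0 for day 2 against day 1, 3 for day 4 against day 3 and 1 for day 7 against day 6. The set test of mitochondrial ribosomal proteins, day 4 against day 1, turned (median 0.0186). Without day 4 as well, counts were 5 in days 5 to 8, 0 for day 2 against day 1, 1 for day 3 against day 2 and 1 for day 7 against day 6.

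Scaling by spike-in counts gave 7580 genes in days 1 to 4, 25 in days 5 to 8, 7565 for day 4 against day 1 (all lower), 9 for day 8 against day 5, 7072 for the difference of changes and 7703 for the means of the series. The median of all genes was then -4.23 for day 4 against day 1, where day 4 is replicate 1 alone, -0.64 for day 8 against day 5 and 2.35 for the means. CG4198, day 4 against day 1, turned to -1.64. For the means of the series Yp3 (0.94), Vm26Ab (0.69), sim (1.38), nos (1.92), pgc (1.92), bcd (1.91), swa (2.07), mei-W68 (1.17), mtrm (1.85), nod (1.77), up (0.73), sls (0.58), Mlc1 (1.35), Act87E (1.01), Hml (0.28), Pxn (1.29), crq (2.09), Hsp27 (1.63), Hr4 (1.12), usp (2.10), Cdc6 (1.90), CycE (1.86), twe (1.44), CycB3 (1.86) and GstD1 (2.12) turned upward, all below that median.

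Leaving out each library gave 0 to 47 genes in days 1 to 4, 0 to 1 in days 5 to 8, 0 to 5 for day 4 against day 1, 0 to 0 for day 8 against day 5, 0 to 1 for the difference of changes and 401 to 809 for the means of the series. For the steps it gave 0 to 4, 0 to 7, 0 to 12, 5 to 107, 0 to 2, 0 to 0 and 0 to 0. Without day 4 replicate 2 the set test of mitochondrial ribosomal proteins, day 4 against day 1, turned (median 0.0202), and the proteasome list, day 8 against day 5, had medians from -0.31 to 0.0678, the highest without day 5 replicate 3. The exact permutation p of the spike-in share stayed between 0.631 and 0.984 in days 1 to 4 and between 0.0540 and 0.238 in days 5 to 8 without each library, and was 0.484 and 0.129 for the share itself. It was 0.467 without the 3 libraries and day 4 replicate 1. Results of named genes, called or not, stayed on their side of the threshold in 78 cases without a filter, 85 with DESeq2 and 91 with DESeq2 size factors. Calls were lost in 8, 1 and 2 cases and gained in 7, 7 and 0. With the eggshell covariate 9 stayed, 66 lost their call, 1 gained a call and 11 reversed. Shallow libraries limit what can be seen: 3 counts are 2.62 CPM in day 3 replicate 1.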

Other observations

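All tests in this part except those of day 8 against day 5 were chosen only after the result was seen.

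Within days 1 to 4 the 3 libraries without spike-in had more RNA of ribosomal protein genes (camera adjusted p = 1.61e-17), mitochondrial ribosomal proteins (5.21e-06), nuclear oxidative phosphorylation (0.000252), mitochondrially encoded mRNAs (0.00203) and detoxification enzymes (0.0210) than the other 7. They had less of follicle cell regulators (1.28e-05), ecdysone response genes (0.00550), Notch and JAK-STAT genes (0.00550) and germline stem cell genes (0.00981). Single genes among those lower were Smr (log2 -1.25), kis (-1.1) and mask (-1.17), which were named after their values were seen. Chorion, vitelline membrane and heat shock genes were not called between these libraries (camera adjusted p = 0.826, 0.993 and 0.993). All of these set tests used only the preset correlation of 0.01, which can call lists of correlated genes too readily. Between the age series the correlation estimated for ribosomal protein genes was 0.791, and their call was lost with it (camera adjusted p = 0.415).

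RNA of other tissues appeared in single libraries. Gut digestive enzyme genes summed to 136 CPM in day 4 replicate 1, 42.9 CPM in day 1 replicate 1 and 33 CPM in day 8 replicate 1, and to at most 11 CPM in the other 19 libraries. Testis and sperm genes summed to 59.3 CPM in day 1 replicate 1 and to at most 5.84 CPM in the other 21. Immune effector genes summed to 43.6 CPM in day 4 replicate 1 and to at most 9.25 CPM in the others. Fat body genes summed to 35.1 to 147 CPM, highest in day 4 replicate 1.

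Other splits of the same libraries were tested for each comparison of at least 3 libraries a side. For the means of the age series, 1 of 100 splits, the real one, gave as many genes (708 called, against at most 6 in the others). These splits moved single libraries between the series, so shuffled days mixed the series and took their difference into the spread. Low counts were therefore likely for any difference that a series shares, whatever its cause, and the splits do not separate causes. For any difference among days 5 to 8, 6 of 100 splits gave as many genes, so chance is not excluded at 1 called gene. The highest of the other splits called 89, which points to a structure of the samples. Within days 5 to 8 same-numbered libraries correlated in their deviations at 0.032 to 0.257 for replicate 1 and 0.113 to 0.236 for replicate 3. Those of replicate 2 lay between -0.0656 and 0.122. Whether that split follows the replicate number was not tested. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Day 3 against day 2 called 0 genes (highest other 5; 10 splits as large), day 6 against day 5 called 1 (highest other 0; 1 as large). Day 7 against day 6, day 8 against day 7 and day 8 against day 5 called 0 (highest other 0; 10 as large). For the gene lists of day 8 against day 5, 8 were called, and 2 of 10 splits, the real one included, gave as many (highest other 9). The count of called lists thus does not exceed that of another grouping of the same libraries.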
